A study of Homo sapiens with 6 samples.

How the data were processed

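Total RNA from HEK293T cells, a human embryonic kidney line, was sequenced in 6 libraries. There were 2 libraries each of wild type (WT) and of the THUMPD2 knockout lines KO1 and KO2. Groups were taken from the genotype labels. Per the labels' protocols, RNA was extracted with TRNzol and libraries were made with the NEBNext Ultra II Directional kit, which keeps the strand of each transcript. The labels give the library type as RF or first-strand. Per the submitters' processing notes, the tools used were Trim Galore, STAR 2.7.1a, HTSeq 0.6.1p1 and limma, with the builds hg38 and GRCh38.p6. The annotation version and the strand setting of the counting are not given in the sources used here. Whether the libraries of a group came from separate cultures is not stated, so p-values measure only the spread between these libraries, which may be technical. There was 1 WT line, so effects of the knockout and other differences between a knockout line and WT cannot be separated by the tests used.

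The authors deposited whole-number read counts per gene symbol for 59087 rows and 6 libraries, with no normalization, and library totals ran from 7414339 to 8391143. The authors also deposited FPKM values, and each library's FPKM equalled the count divided by the gene size in the table and by 1 scaling factor per library. The authors' deposited table further held log2 fold changes of the 4 knockout against the 2 WT libraries. It also gave p-values and q-values, which the authors computed per the file headers. Every test reported here used the deposited counts. The FPKM values were used only to find the scaling, and the fold changes and q-values only for the comparison with the authors' deposited table.

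Counts were tested with the edgeR 4.0.16 quasi-likelihood F test in R 4.3.3, with TMM scaling and filterByExpr, which kept 14184 rows. All 6 libraries entered 1 fit of 3 groups without covariates, with 3 residual and 31.9 prior degrees of freedom. The biological coefficient of variation was 7.57%. Contrasts were KO1 against WT, KO2 against WT, the mean of both lines against WT, and KO1 against KO2. A row was called at a Benjamini-Hochberg adjusted p under 0.05, and called in both lines when each line passed with the same sign. Because both lines share the WT libraries, 20 simulations of unchanged groups were run against those controls. With 2 WT libraries the controls could not be split, so part of the overlap between lines may come from them.

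The 30 gene lists were tested with camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation. The fry test was run beside it, and p-values were adjusted over the lists. The clustered protocadherins had 1 tested row and no list test. Lists, tests, the rule for named rows and all alternatives except those marked as added were fixed before the data were examined. The rule took THUMPD2 and its partner TRMT112, and METTL16, SART3, LARP7, MEPCE and USB1 whatever their values. Among rows called in both lines, with a mean CPM of at least 1 and no clone-based, microRNA, LINC or LOC symbol or gene identifier, it took the 10 highest and 10 lowest by the mean of both lines and the 5 most abundant in each direction. For each list it took up to 4 members called in both lines, by the smallest p in the mean of both lines, or where there were none the 2 of smallest p as values. It also took the 5 highest and 5 lowest rows among those called between KO1 and KO2. It gave 112 rows, of which 111 were tested, and the values of some of them are not reported here.

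Rows were placed on GRCh38 with GENCODE v29 by symbol, 56239 directly and 324 through a current symbol. Another 176 symbols belonged to several genes and 2348 were not placed. Row counts were then set against genes annotated on the opposite strand, a step added after low counts of abundant genes had been seen. A row was assigned to 1 opposite-strand gene when at least 100 of its exonic bases lay over that gene's exons and these made up at least 80% of its opposite-strand overlap. This reached 4909 genes through a tested row, 3352 of them protein-coding. Genes named through such a row, outside the rule, were chosen after their values were seen. Shifts along the genome were taken as medians in 10 Mb bins with at least 15 rows of mean count 50 or more. A fold against a group with no reads is a lower bound, computed with 3 counts over that group. Bounds cover counting error only, since reads without molecular identifiers are not independent molecules.

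Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, other filters, the replicate number as a block, a fold threshold of 1.2, fits of the compared libraries only, a 2-group fit and leaving out each library. Added after seeing the data were an offset by 10 Mb bin, the same with the mitochondrial genome as a bin of its own, a restriction to rows over opposite-strand exons, and list tests read through the opposite-strand gene. The count of calls kept in each of the 6 fits that leave out 1 library was also added then. Rows in bins with fewer than 15 rows of mean count 50 or more received no bin offset. For such rows the bin offset did not test a shift of their region. A fit without 1 library leaves 1 library in a group, which is assumed to vary like the other groups. The procedure was tested on simulated data with 200 changed rows among 14184. At a 2-fold change it recovered 50.5% for KO1 against WT, 39% for KO2 against WT, 43.5% for both lines, 58% for the mean of both lines and 51.5% for KO1 against KO2. Among changed rows with a mean count of at least 50, the recovery was 95.2%, 89.5%, 86.0%, 93.4% and 93.5% in the same order. At a 1.5-fold change it was 26.5% for KO1 against WT and 14% for both lines over all rows. False calls made up 10.2% of the calls in KO1 against WT at 1.5-fold, 4.72% at 2-fold and 6.70% at 4-fold. For KO2 against WT they made up 14%, 4.88% and 8.79%, and for both lines 6.67%, 1.14% and 0.671%. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for positions, bins and figures. Splicing of single introns was not analysed here, since the counts are per gene.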

Results

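HEK293T cells of wild type and of 2 THUMPD2 knockout lines were compared by RNA sequencing, with 2 libraries per group. THUMPD2 is an RNA methyltransferase that acts on the U6 spliceosomal RNA, and the stated purpose was to find genes and splicing events altered by its loss, with the second line as a check of reproducibility. Total counts were 7619064 and 8085598 in WT, 7539788 and 7414339 in KO1, and 7926552 and 8391143 in KO2. Replicates differed by more than counting noise, with a chi-square per degree of freedom of 2.46 in WT, 4.13 in KO1 and 2.30 in KO2. On the first principal component, 44.7% of the variance, WT stood apart from both lines. On the second, 28.2% of the variance, KO1 and KO2 lay on opposite sides.

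THUMPD2 (ENSG00000138050.14, chromosome 2, 39736060 to 39779267 on the minus strand of GRCh38) had 1 and 2 reads in WT, 3 and 0 in KO1, and 0 and 1 in KO2. These counts were too few to test, and no row lay over its exons on the opposite strand, so the genotype labels were not checked by the target. TRMT112, which encodes the activating partner of THUMPD2 and other methyltransferases, had a row at −0.16 ± 0.08 (log2 fold change ± SE, n = 2 against 2) in KO1, not called. It fell by 0.60 ± 0.08 in KO2, with a Benjamini-Hochberg adjusted p of 2.95e-07 by the edgeR quasi-likelihood test. The TRMT112 row shares 284 exonic bases with ESRRA on the other strand. The ESRRA row, over those TRMT112 exons, was at −0.07 in KO1 and −0.01 in KO2, not called in either.

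Abundant genes had low counts, while rows on the strand opposite to them had high counts. The GAPDH row (chromosome 12, 6533927 to 6538374, plus strand) held 168.5 ± 30.02 reads (mean ± SD, n = 6). AC006064.4, which lies over 422 of its exonic bases on the minus strand, held 131125 ± 7525. Counts over the opposite strand were 946 times those of the gene's own row for TUBA1B, 587 times for TUBB and 73.2 times for VIM. For EEF1A1, a translation elongation factor, the ratio was 0.195, the other way. Its opposite row, AL121972.1, begins at 73523618 and shares only 180 exonic bases, where this minus-strand gene starts. That ratio therefore covers only this end of the gene. The EEF1A1 row itself held 461.7 reads, and the ACTB row, with no opposite row, 421.2. Rows with exons over opposite-strand exons made up 22.2% of placed rows and held 89.9% of all counts. Rows annotated as antisense held 44.1%, and the cytosolic ribosomal protein rows 0.252%. Protein-coding rows with at least 100 such bases had a median mean count of 40.9 (5054 rows), against 5.67 (8855 rows) where no gene lay opposite. Rows that share at least 100 exonic bases with an opposite-strand gene are therefore given with that gene. A symbol said to be higher or lower stands for the row of that name, and its change is not stated as a change of the gene.

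**Figure D1:**
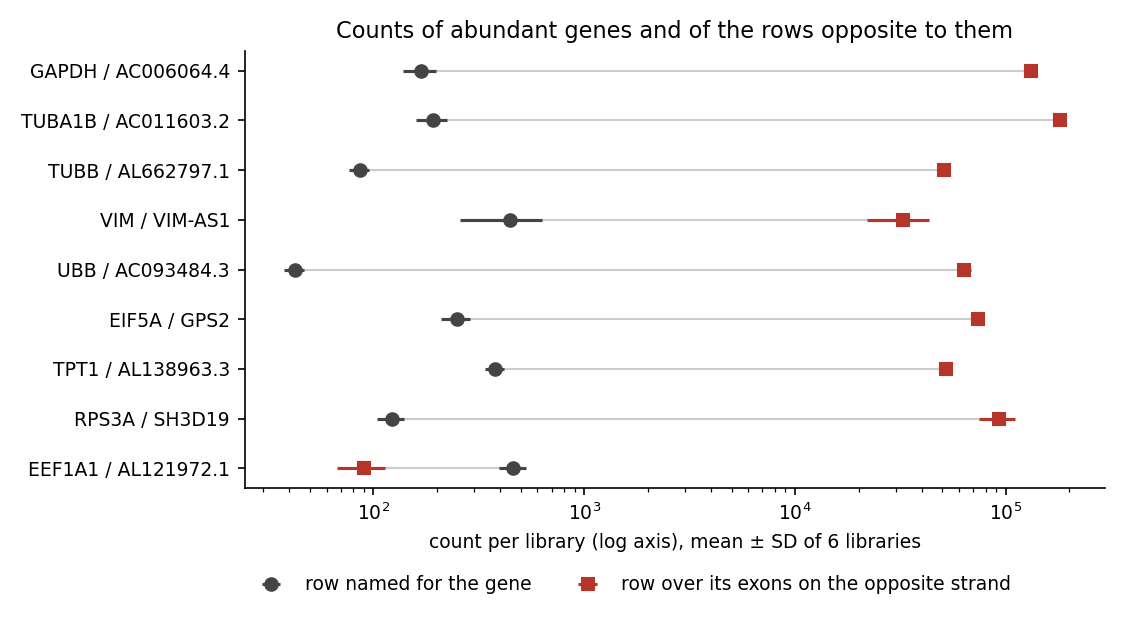
Counts per library (log axis, mean ± SD of 6 libraries) of rows named for abundant genes and of the rows over their exons on the opposite strand. The row over GAPDH holds 131125 reads on average and the GAPDH row 168.5. EEF1A1 differs, with 462 in its own row and 90.0 opposite, where only 180 exonic bases are shared.

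In KO1 against WT, the row GPR39, over 1180 exonic bases of LYPD1 (a membrane-anchored protein), rose 121-fold from 19 and 28 reads to 2616 and 2775. PCAT1, over FAM84B, rose 41.4-fold. AC015712.2, over ALDH1A3 (an enzyme of retinoic acid synthesis), fell to 19 and 10 reads from 469 and 519, and HDDC2, over TPD52L1, fell to 50 and 60 from 1005 and 1052. The row NHLH2, named for a neuronal transcription factor, had no reads in WT and 172 and 154 in KO1, at least 115-fold higher. PUDP went the other way, with 40 and 63 reads in WT and none in KO1, at least 32.5-fold lower. In all, 1469 rows were higher and 1881 lower, and 1182 of them changed at least 2-fold. With upper-quartile factors the split was 1941 higher and 1549 lower, so which direction prevailed depended on the scaling.

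In KO2 against WT, CCDC152, over SELENOP (the plasma selenium carrier), rose 89.4-fold from 8 and 11 reads to 876 and 1014. AC027451.1, over KCNV1 (a potassium channel subunit), went from no reads to 75 and 79, and the row FSTL5, over AC104793.1, from 2 and 0 to 362 and 347. SPRYD4, over GLS2 (a mitochondrial glutaminase), fell to 6 and 13 reads from 471 and 486. SSC4D, over ZP3, had 107 and 97 reads in WT and none in KO2, at least 74.6-fold lower. In all, 1934 rows were higher and 2184 lower, and 1435 of them changed at least 2-fold. With upper-quartile factors the split was 2088 higher and 2022 lower, and with the bin offset 1848 higher and 1661 lower.

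The second line was made to check reproducibility, and large changes were shared by both lines. NCAM1-AS1, over the neural adhesion gene NCAM1 (chromosome 11, 112961247 to 113278436), rose by 4.36 ± 0.17 in KO1 and 4.30 ± 0.17 in KO2 (log2 ± SE, n = 2 against 2). AC110015.1, over CDH2 (N-cadherin), rose 2.84-fold and 2.80-fold, while AC099314.1, over CDH1 (E-cadherin), fell by 1.72 ± 0.26 and 1.53 ± 0.25. CRYZ, over 257 exonic bases of TYW3 (an enzyme of the wybutosine modification of tRNA), rose 4.78-fold and 4.19-fold. AC091588.3, over the transcription factor gene GATA6, rose 3.33-fold and 2.41-fold. SLC8A1-AS1, over the sodium-calcium exchanger gene SLC8A1, had no reads in WT, 191 and 229 in KO1 and 110 and 127 in KO2. It was at least 148-fold and 71.97-fold higher. Its annotated start lies 7186 bases from THUMPD2, but it runs on to 40255209. SLC8A1 itself lies from 40097270 to 40611053, so the reads need not lie near THUMPD2. Of the 8 tested rows within 1 Mb of THUMPD2, SLC8A1-AS1 alone was called in both lines. Among rows that fell, FADS1, over the desaturase gene FADS2, dropped by 2.56 ± 0.10 and 2.08 ± 0.09, and AL356652.1, over PROCR (the endothelial protein C receptor), dropped by 2.28 ± 0.08 and 1.70 ± 0.08. GRK6, over F12 (coagulation factor XII), fell 2.72-fold and 5.01-fold. LBX2-AS1, over the homeobox gene LBX2, fell from 134 and 176 reads to 1 and 4 in KO1 and 4 and 4 in KO2. These calls held in each alternative fit of both lines, including the fits without 1 library. The bins of CRYZ, AC110015.1 and AC091588.3 had too few rows for the bin offset. For these rows that fit therefore did not test a shift of the region.

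**Figure D2:**
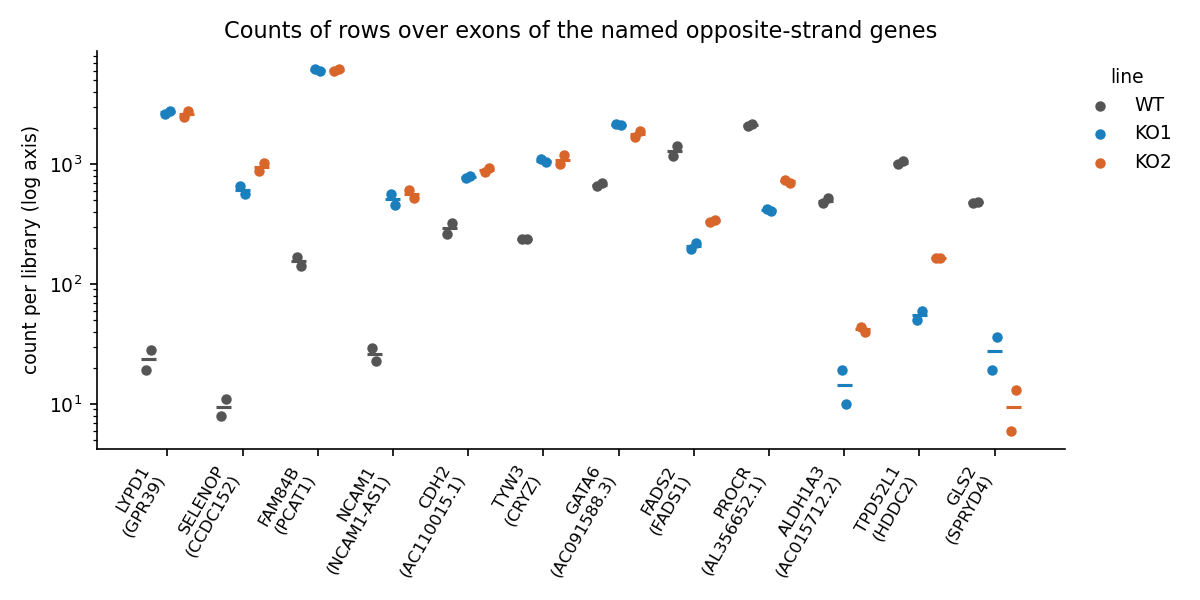
Counts per library (log axis) of 12 rows over exons of the named opposite-strand genes, with points for the 2 libraries and a line at the mean of each group. The row over LYPD1 has 19 and 28 reads in WT and between 2477 and 2779 in each knockout library.

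In total 821 rows were higher and 1095 lower in both lines, 532 of them at least 2-fold in each. Lists of independent calls would share 200.3 higher and 289.63 lower rows. Unchanged groups simulated against the shared WT libraries gave a mean of 0.25 rows. These simulations had only 0.95 calls in KO1 and 1.15 in KO2 on average. They therefore cannot show how many shared calls come from the WT libraries or the single WT line. Whichever library was left out, 974 of the 1916 calls were kept with their direction in both lines, 389 higher and 585 lower. Another 161 rows were called in opposite directions. The covariance of the log2 fold changes was 0.615, against 0.0778 in the simulations, and their correlation across rows was 0.659 against 0.506. Across rows, which are not independent replicates, 71.8% had the same sign against 66.7%. With upper-quartile factors the split was 1019 higher and 901 lower. With the 10 Mb bin offset 1560 rows were called in both lines, 757 higher and 803 lower, and 1299 of these were among the 1916. Bin medians of KO1 and KO2 against WT correlated at 0.654, to which the shared WT libraries may add. Part of the shared calls may therefore follow regional shifts present in both lines. Through the opposite-strand gene, 278 protein-coding genes lay under rows higher in both lines and 512 under rows lower.

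**Figure D3:**
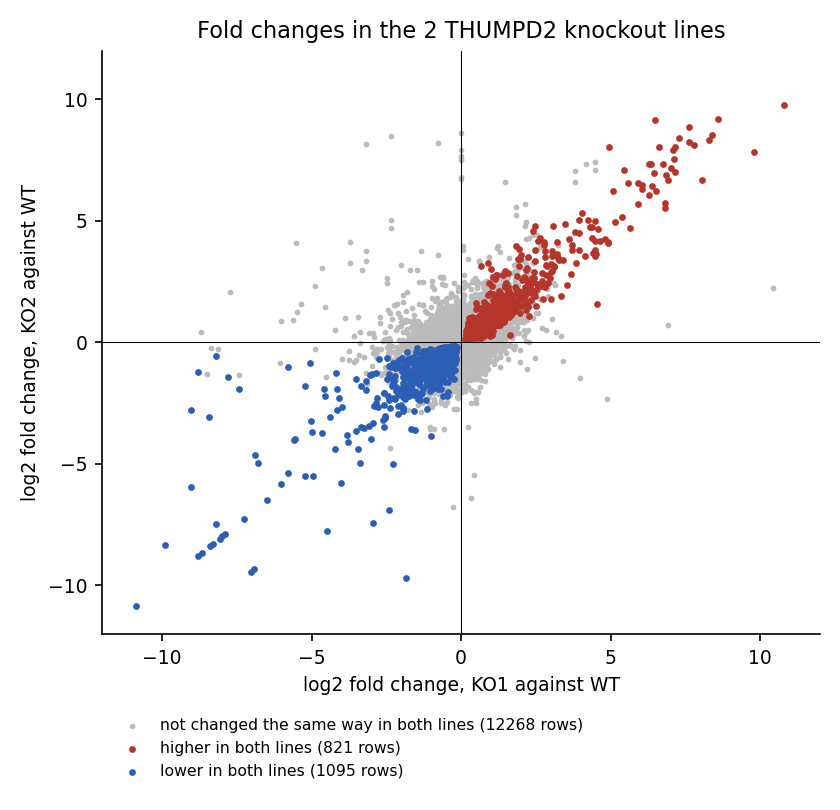
Log2 fold change of each tested row in KO1 against WT (horizontal) and KO2 against WT (vertical). Coloured points are the 821 rows higher and the 1095 rows lower in both lines.

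Among rows with standard symbols, a block of type I keratin rows on chromosome 17 lost all reads in both lines. KRT38 had 222 and 236 reads in WT and none in any knockout library, at least 144-fold lower in KO1 and 168-fold in KO2. KRT32 (42 and 68 reads in WT), KRT43P (41 and 36), KRT35 (14 and 49) and KRT36 (10 and 12) were also at 0 in all 4 knockout libraries, and by DESeq2 KRT35 was not called, with adjusted p-values of 0.373 and 0.322. Without WT library 2 it had too few reads to test. They span 41436446 to 41492546 on the minus strand, and KRT19, further along at 41523617, was at 0.03 ± 0.54 and −0.07 ± 0.54. TECPR1 fell from 228 and 239 reads to 9 and 5 in KO1 and 8 and 3 in KO2. HNRNPCP4, with 40 and 26 reads in WT, was at 0 in both lines. RPS16P9, a pseudogene whose reads may be shared with its parent gene, had 327 and 368 reads in WT and 2, 0, 2 and 2 in the knockout libraries. In the other direction, SPINK5, THBS2, DPYD-AS1 (over DPYD), GRM7-AS3, OR8D1, RBMS3 and CHRM3-AS2 (over CHRM3) had no reads in WT and between 9 and 51 in each knockout library. JAKMIP2-AS1, over JAKMIP2, rose from 0 and 2 reads to 336 and 370 in KO1 and 437 and 481 in KO2, and RAC1P9 from 0 and 1 to 159 and 154 in KO1 and 67 and 74 in KO2. Among abundant rows called in both lines, JSRP1, over OAZ1, rose by 0.20 and 0.36, and PCBP1-AS1, over PCBP1, by 0.21 and 0.30. CDKN2B-AS1, over 341 exonic bases of the cell cycle inhibitor gene CDKN2A, fell by 0.52 and 0.23. With an offset for the 10 Mb bin, GATC, over the splicing factor gene SRSF9, went from 0.28 and 0.30 to 0.01 and 0.04, and ZACN, over EXOC7, from −0.42 and −0.45 to −0.19 and 0.11, and their calls in both lines ended. TSIX, over XIST, at 0.15 and 0.16, was not called in KO1 without KO1 library 1 (0.05) or WT library 1 (0.13).

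Lists of splicing factors were examined because U6 acts in the spliceosome. COX20, over 3502 exonic bases of HNRNPU (a nuclear RNA-binding protein), rose by 0.87 ± 0.07 and 1.12 ± 0.07. Its bin at the end of chromosome 1 had too few rows for the bin offset. In the bin before it, from 230000001 to 240000000, the medians were 0.83 and 0.86. A shift of the region was therefore not separated from the rise of COX20. Of 52 SR protein and hnRNP rows tested by name, 5 were higher in both lines and none lower, 5 also adjusted over the list alone, and SRSF9 (over GATC, 0.70 and 0.48), SON (over DONSON, 0.63 and 0.56) and CLK3 (over EDC3, 0.39 and 0.27) kept the call without any 1 library. CLK3 was at 0.05 and −0.05 with the bin offset and not called. GATC, which lies over SRSF9 and is the more abundant of the pair, was at 0.28 and 0.30, and its call ended with the bin offset, at 0.01 and 0.04. The rows DONSON (0.43 and 0.13, over SON), EDC3 (0.70 and 1.06, over CLK3) and AL354733.3 (0.09 and 0.09, over HNRNPK) were not called in both lines. HNRNPK, at 0.71 and 0.82, was not called in KO1 without KO1 library 1 (0.51) or WT library 2 (0.53). PTBP1, at 0.55 and 0.52 and named after its values were seen, was not called in KO1 without KO1 library 1 (0.43) or WT library 1 (0.42), nor in KO2 without KO2 library 1 (0.42) or WT library 1 (0.40). Of 27 rows of the U6 and tri-snRNP list, USB1 (over ZNF319), named for the enzyme that trims the end of U6 RNA, was the 1 lower in both lines (−0.67 ± 0.18 and −0.67 ± 0.18) and none was higher. USB1 was not called in KO1 without KO1 library 2 (−0.58) or in KO2 without KO2 library 1 (−0.59). None of 25 rows of the U1, U2 and Sm list was called in both lines by edgeR, and 1 of 23 of the Prp19 and catalytic list was lower, PPIE at −1.09 and −0.36. PPIE was not called in KO2 without either KO2 library (−0.28 and −0.42), without WT library 1 (−0.26) or with the bin offset (−0.25). Adjusted over the list alone, the U6 list kept its 1, the Prp19 list had none, and the U1, U2 and Sm list had 1 higher. The 2 rows that the rule took from the U1, U2 and Sm list, SF1 (0.54) and SNRNP70 (0.59), were called higher in the mean of both lines. Those calls ended without WT library 2 for SF1 (0.50) and WT library 1 for SNRNP70 (0.45). In KO2, SNRNP70 was called at 0.72, and not without KO2 library 1 (0.49).

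The row THUMPD3, named for a paralog of THUMPD2 and lying over THUMPD3-AS1, rose by 0.92 and 1.11, the 1 called in both lines among 8 rows of TRMT112 partners and THUMP-domain proteins. Of 17 nonsense-mediated decay rows 1 was called, SMG6, which lies over the tumour suppressor gene HIC1 and fell by 2.09 and 2.62. Of 10 minor spliceosome rows 1 was called, SNRNP35 (over RILPL1, 0.34 and 0.47). SNRNP35 was not called in KO1 without KO1 library 2 (0.23) or WT library 1 (0.24), nor with the bin offset (0.07). Counts adjusted over the list alone were the same for these 3 lists. By camera, none of the 7 splicing, decay and partner lists passed in the mean of both lines, with the lowest adjusted p at 0.543 for the U1, U2 and Sm list. METTL16, named for a methyltransferase of U6, was at −0.27 ± 0.74 and 0.57 ± 0.67, SART3 at 0.28 and 0.39, LARP7 (over AC106864.1) at 0.83 and −0.80, and MEPCE (over ZCWPW1) at 0.57 and 0.00, none called in either line. MIR302CHG, over LARP7, rose by 0.53 in KO1 and was at 0.01 in KO2.

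Read through the opposite-strand gene, 2 of 17 SR protein and hnRNP genes lay under rows higher in both lines, HNRNPU and SRSF9, and none under rows lower. None of 7 genes of the U6 list, 4 of the U1, U2 and Sm list and 6 of the partner list lay under a row called in both lines by edgeR. Under rows lower in both lines lay 1 of 6 genes of the Prp19 list, PRPF18 (RPL6P24, a pseudogene row, at −0.74 and −1.17), and 2 of 5 minor spliceosome genes, SNRNP25 (POLR3K, −0.63 and −0.68) and TXNL4B (AC009087.1, −0.47 and −0.37). Of 4 decay genes 1 lay under a higher row, RNPS1 (AC009065.4, 0.33 and 0.44). The KO1 calls over PRPF18 (−0.66), SNRNP25 (−0.56) and RNPS1 (0.27) ended without KO1 library 2, and that over PRPF18 also with the bin offset (0.29). Without WT library 2 the calls over SNRNP25 (−0.56 and −0.61) and TXNL4B (−0.34 and −0.23) ended in both lines and that over RNPS1 in KO1 (0.30). The call over TXNL4B also ended in KO1 without KO1 library 1 (−0.43) and in KO2 without either KO2 library (−0.44 and −0.29).

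Retinal lists were examined because the study's title names retina degeneration. Rows over ADAMTS9 and CNN2, both at loci of age-related macular degeneration, fell in both lines, that over ADAMTS9 by 1.25 ± 0.24 and 1.23 ± 0.24 and that over CNN2 by 0.96 ± 0.10 and 1.13 ± 0.10. By row name, 2 of 18 tested rows of that list were higher in both lines and 2 lower, and 2 and 1 adjusted over the list alone. The row SLC16A8, named for a lactate transporter gene of the pigment epithelium, rose by 0.65 and 1.07, and NPLOC4, over TSPAN10, fell by 0.73 and 1.05. NPLOC4 was not called in KO1 with the bin offset (−0.42). VTN, at 0.82 and 0.73, was not called in KO1 without KO1 library 2 (0.66) or with the bin offset (0.35). MMP9 (over SLC12A5-AS1), at −0.74 and −1.37, was not called in KO1 without WT library 1 (−0.47) or without either KO1 library (−0.69 and −0.78).

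Of 34 inherited retinal dystrophy rows, 2 were higher and 4 lower in both lines, also adjusted over the list alone, and WHRN, at −2.20 and −1.40, was the 1 that kept its call whichever library was left out. RPGRIP1, at −0.81 and −1.22, was not called in KO1 without KO1 library 2 (−0.75) or WT library 1 (−0.74). IMPDH2, at −0.68 and −0.22, was not called in KO2 without either KO2 library (−0.17 and −0.27) or WT library 2 (−0.13). MAK (over TMEM14B), at 0.77 and 0.37, was not called in KO2 without KO2 library 1 (0.21), WT library 1 (0.30) or WT library 2 (0.44), and was at 0.18 and 0.02 with the bin offset. FSCN2 (−0.66 and −0.65) and PRPS1 (0.63 and 0.71), named after their values were seen, were not called in either line without WT library 2 (−0.56 and −0.54) and without WT library 1 (0.51 and 0.58). FSCN2 was also not called without KO1 library 2 (−0.47) or KO2 library 2 (−0.44), nor was PRPS1 in KO1 without either KO1 library (0.59 and 0.67). Of 17 photoreceptor and pigment epithelium rows, 4 were lower in both lines and none higher, also adjusted over the list alone. The row ROM1 (over EML3), named for a photoreceptor disc protein, fell by 0.83 and 0.78. PDE6C, at −1.71 and −0.82, was not called in KO2 without KO2 library 1 (−0.68) or with the bin offset (−0.51). PMEL (over CDK2), at −0.34 and −0.21, was not called in KO2 without either KO2 library (−0.21 and −0.20) or WT library 1 (−0.16). GNAT1, with 19 and 18 reads in WT and between 2 and 6 in each knockout library, was not called in KO1 without KO1 library 2 (−1.57), WT library 1 (−2.02) or WT library 2 (−2.20). The camera adjusted p of the macular degeneration, dystrophy and photoreceptor lists was 0.761, 0.984 and 0.126 in the mean of both lines.

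Of the p53 targets, AL390208.1, over SESN1, rose by 0.49 ± 0.08 and 0.74 ± 0.08. DINOL, over 146 exonic bases of CDKN1A (the cell cycle inhibitor p21), was at 1.94 ± 0.60 and 3.86 ± 0.49, and without WT library 1 its KO1 value was 1.48 and not called. Of the ATF4 targets, DDIT4-AS1, over DDIT4, rose by 0.77 ± 0.06 and 0.34 ± 0.06, and VLDLR-AS1, over the lipoprotein receptor gene VLDLR, by 0.97 ± 0.16 and 0.98 ± 0.16. Of the unfolded protein response, AC092069.1, over the chaperone gene CALR, fell by 0.63 ± 0.06 and 0.38 ± 0.06, and SMARCB1, over DERL3, rose by 1.03 and 0.67. Of the interferon-stimulated genes, AL671883.2, over HLA-B (a class I antigen-presenting molecule), fell by 1.34 ± 0.06 and 0.85 ± 0.06. The overlapping rows PARP9 and DTX3L, each over the other gene, fell from 48 and 82 and from 31 and 30 reads in WT to 3 or fewer in every knockout library. By row name, 1 of 20 p53 targets was higher in both lines, AEN, with 0 and 3 reads in WT and 11 to 22 in the knockout libraries. Of 22 ATF4 targets 2 were higher, SLC1A5 (over AC008622.2) at 0.48 and 0.57 and VLDLR at 1.07 and 1.502. SLC1A5 was not called in KO1 without WT library 2 (0.46). The row named VLDLR was not called in KO1 without KO1 library 1 (0.84), WT library 1 (1.07) or WT library 2 (1.07), nor in KO2 without KO2 library 2 (1.09). Of 22 unfolded protein response rows 1 was lower, SYVN1 (over MRPL49) at −0.24 and −0.56, not called in KO1 without KO1 library 1 (−0.18) or WT library 2 (−0.18). PARP9 and DTX3L were the 2 lower among 15 interferon-stimulated rows. None of 17 heat shock rows was called in either direction in both lines by edgeR, with CRYAB (over HSPB2) at 1.41 and 1.72 and STIP1 at −0.11 and −0.15. For these 5 lists the counts adjusted over the list alone were the same. Of these 5 lists the ATF4 list alone passed camera in KO1, with an adjusted p of 0.015 that became an adjusted p of 0.697 with an estimated correlation. In the mean of both lines its adjusted p was 0.316, as was that of the p53 list, and those of the unfolded protein, heat shock and interferon lists were 0.984, 0.761 and 0.575. By fry, which tests whether the rows of a list move on balance one way and does not compare them with other rows, the ATF4 list passed in KO1 (adjusted p 0.0497), and the p53 and ATF4 lists in the mean of both lines (0.0400 each).

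Among metabolic genes, IDI2-AS1, over IDI1 (an enzyme of isoprenoid synthesis), fell by 0.90 ± 0.08 and 0.65 ± 0.08. It lies on chromosome 10, where the median of rows was −0.48 in KO1 and −0.35 in KO2. Its bin had too few rows for the bin offset, so a shift of its region was not tested. In the respiratory chain, HIF1AN, over the complex I gene NDUFB8, fell by 0.42 and 0.50, GABPA, over the ATP synthase gene ATP5PF, fell by 0.28 and 0.26, and CFAP126, over the succinate dehydrogenase gene SDHC, rose by 0.34 and 0.55. Through the opposite-strand gene, 3 genes of that list lay under rows higher in both lines and 2 under rows lower. Of these, 1 higher and 2 lower kept the call whichever library was left out. With the bin offset the calls over NDUFB8 (0.13 and −0.01) and SDHC (−0.07 and 0.06) ended. By row name, MVK (over MMAB), named for mevalonate kinase, rose by 0.47 and 0.39, and PKM, named for pyruvate kinase, rose by 0.78 and 0.62, with 0.33 in KO2 and no call there under the bin offset. Of 15 cholesterol synthesis rows 3 were higher in both lines and none lower, of 28 glycolysis and hypoxia rows 1 was higher and 1 lower, of 35 replication rows 3 were higher and 1 lower, of 38 mitosis rows 2 were higher and none lower, and of 54 nuclear-encoded respiratory chain rows 2 were higher and 2 lower. Adjusted over the list alone the counts were the same for cholesterol, glycolysis and mitosis, 1 higher and 1 lower for replication, and none higher and 1 lower for the respiratory chain. Apart from MVK and PKM, each of these calls ended in at least 1 line without WT library 1 or WT library 2. Among them, TYMS (over ENOSF1), at −0.69 and −0.26, was not called in KO2 without either KO2 library (−0.21 and −0.30) or either WT library (−0.26 and −0.26), and MCM3, at 0.73 and 1.00, was not called in KO1 without KO1 library 2 (0.55) or WT library 1 (0.62). PRC1 (over PRC1-AS1), at 1.66 and 1.199, was not called in KO1 without KO1 library 1 (1.11) or in KO2 without KO2 library 1 (1.09) or WT library 2 (0.97). NDUFS7 (over AC005329.1), at −0.66 and −0.45, was not called in KO2 without WT library 2 (−0.35). The camera adjusted p of the replication, mitosis, cholesterol, glycolysis and nuclear respiratory chain lists was 0.598, 0.826, 0.598, 0.543 and 0.575 in the mean of both lines.

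Another 8 members of these lists were called in both lines and lost a call when certain single libraries were left out. MCM4, named for a subunit of the replicative helicase, at 0.79 and 1.19, was not called in KO1 without KO1 library 1 (0.42), nor in either line without WT library 1 (0.37 and 0.76). GINS3 (over AC009118.2), at 0.44 and 0.47, was not called in KO1 without KO1 library 2 (0.35) or WT library 1 (0.53), in KO2 without either KO2 library (0.47 and 0.49), or in either line without WT library 2 (0.35 and 0.39). UBE2S, at 0.60 and 0.72, was not called in KO1 without KO1 library 2 (0.54) or in either line without WT library 1 (0.49 and 0.60). DHCR7, at 1.13 and 0.86, was not called in KO1 without KO1 library 1 (0.72), nor in KO2 without KO2 library 1 (0.89), KO2 library 2 (0.84), WT library 1 (0.91) or WT library 2 (0.81). BNIP3L (over PNMA2), at −0.46 and −0.43, was not called in KO1 without KO1 library 1 (−0.40), in KO2 without KO2 library 2 (−0.34), or in either line without WT library 1 (−0.48 and −0.45) or WT library 2 (−0.45 and −0.41). COX5A, at 0.95 and 1.12, was not called in KO1 without KO1 library 2 (0.88) or in either line without WT library 1 (0.55 and 0.72). ATP5MC3 (over AC096649.2), at 0.56 and 0.63, was not called in KO1 without KO1 library 1 (0.38), in KO2 without KO2 library 1 (0.58), or in either line without WT library 1 (0.34 and 0.41). ATP5MF, at −0.46 and −0.95, was not called in KO1 without KO1 library 1 (−0.47), KO1 library 2 (−0.46), WT library 1 (−0.54) or WT library 2 (−0.39).

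Of 12 neuronal rows 2 were higher in both lines by name, and 6 were higher and none lower in KO2. NEFM (over AF106564.1), a neurofilament row named after its values were seen, was at −2.48 in KO1 and 2.65 in KO2. By fry the neuronal list passed in KO2 (adjusted p 0.0244) and in the mean of both lines (0.0382). By camera, which compares a list with the other rows, it did not, at 0.0961 and 0.541. In KO1, where it passed neither test, its median was −0.15 and its mean 0.22. NCAM1 (over NCAM1-AS1) went from 1 and 2 reads to between 34 and 52, and INSM1, at 2.46 and 1.91, was not called in KO1 without KO1 library 1 (2.07), in KO2 without KO2 library 2 (1.52), or in either line without WT library 2 (1.44 and 0.90). MAL2-AS1, over the epithelial gene MAL2, rose by 3.95 ± 0.41 and 5.05 ± 0.36, opposite to CDH1, and none of 8 epithelial rows passed in both lines by name. KRT18, over KRT8, was at 0.44 and 1.57, called in KO2. SRFBP1, over the collagen crosslinking gene LOX, rose by 1.02 ± 0.15 and 1.39 ± 0.14. Of 21 mesenchymal rows, 1 was higher, TWIST1 (over AC003986.2) by 1.49 and 1.32, and 1 lower, ZEB1 (over ZEB1-AS1) at −0.54 and −0.83. ZEB1 was not called in KO1 without WT library 1 (−0.46). It lies on chromosome 10, with medians of −0.48 and −0.35, in a bin with too few rows for the bin offset. None of 12 blood cell rows passed in both lines, with SPI1 at −1.13 and −0.82. AC126407.1, over the imprinted gene MKRN3, rose by 3.21 ± 0.28 and 4.13 ± 0.26. Of 10 imprinted rows, GNAS (over GNAS-AS1) was higher (0.84 and 0.65) and INPP5F lower (−1.73 and −1.23). None of 3 germline rows passed in both lines, with SYCP3 (over CHPT1) at 0.06 and 0.00. Of these, MAGEA8 was called higher in the mean of both lines, at 2.10. It was not called there without KO1 library 1 (1.48), KO2 library 1 (1.94), WT library 1 (2.15) or WT library 2 (2.05). The only tested row of the clustered protocadherins, PCDHGC3, had 5 and 4 reads in WT and between 15 and 28 in each knockout library. It was not called in KO1 without either KO1 library (1.83 and 1.84), WT library 1 (2.05) or WT library 2 (1.63), nor in KO2 without KO2 library 2 (1.96). Of 15 small nucleolar RNA host gene rows 1 was higher, SNHG17 at 1.35 and 0.92, and none adjusted over the list alone. SNHG17 was not called in KO2 without either KO2 library (0.83 and 1.02), WT library 1 (1.14) or WT library 2 (0.72). Elsewhere in this group the counts adjusted over the list alone were the same. In the mean of both lines the lowest camera adjusted p of these lists was 0.316, for the host genes, and it was 0.761, 0.598 and 0.598 for the epithelial, mesenchymal and blood lists.

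Read through the opposite-strand gene, a reading added after the data were seen, none of 26 lists passed camera in the mean of both lines. In KO2 the neuronal list (3 genes, adjusted p 0.00271) and the mesenchymal list (7 genes, 0.0338) passed upward, with an adjusted p of 0.546 for each with an estimated correlation. The Prp19 and macular degeneration lists (0.0370 each) passed downward there, with an adjusted p of 0.546 and 0.643 with an estimated correlation. The ATF4 list of 10 genes passed upward in KO1 (0.0367), with an adjusted p of 0.963 with an estimated correlation, and was higher in KO1 than in KO2 (0.00191), with an adjusted p of 0.662 with an estimated correlation. By fry 2 of these lists passed in KO1, 8 in KO2, 10 in the mean of both lines and 10 between the lines.

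In WT, mean CPM was 8318.5 for MT-ND6 and 4030.3 for MT-TS1, both on the minus strand. On the plus strand it was 6146.1 for MT-ND5, 982 for MT-CO1 and 957.1 for MT-RNR2. Which strand's transcripts the mitochondrial rows hold was not settled, so their changes are not stated as changes of the mRNAs. Of 12 tested rows of mitochondrially encoded respiratory chain genes, 11 were lower in both lines, also adjusted over the list alone, and MT-ND4L was not called. The camera adjusted p of this list was 9.6e-06 in KO1, 3.4e-05 in KO2 and 8.2e-06 in the mean of both lines, with an adjusted p of 0.697, 0.880 and 0.682 with an estimated correlation. By fry the adjusted p was 0.0497, 0.0497 and 0.0382. MT-ND1 fell by 1.40 ± 0.07 and 1.53 ± 0.07, MT-ND2 by 1.30 ± 0.08 and 1.24 ± 0.07, MT-CYB by 1.03 and 1.08, MT-CO1 by 0.91 and 1.04, MT-ND4 by 0.98 and 0.79, and MT-ND5 by 0.69 and 0.90. Whichever library was left out, 8 of the 11 kept the call. MT-CO2, at −0.52 and −0.31, was not called in KO2 without KO2 library 2 (−0.19) or WT library 2 (−0.23), and MT-ND3, at −0.36 and −0.56, was not called in KO1 without KO1 library 2 (−0.31) or WT library 2 (−0.26). MT-ND6, the respiratory chain gene on the minus strand, was at −0.14 ± 0.05 and −0.17 ± 0.05. It was not called in KO1 without KO1 library 1 (−0.06), in KO2 without KO2 library 2 (−0.11), or in either line without WT library 2 (−0.08 and −0.11). Of the minus-strand tRNA rows, MT-TQ fell by 2.17 and 1.83, MT-TE by 1.83 and 1.40 and MT-TA by 3.36 and 3.48, and MT-TY was lower in both lines at −0.53 and −1.196. MT-TP, at −0.22 and −1.52, was not called in KO1 without KO1 library 1 (−0.15) or WT library 1 (−0.18). MT-TS1, the most abundant of them, rose by 0.54 in KO1, with a Benjamini-Hochberg adjusted p of 1.5e-11 by edgeR. It was at −0.05 in KO2, not called, and at 0.25 in the mean of both lines, higher. The ribosomal RNA rows MT-RNR1 (0.17 and 0.06) and MT-RNR2 (0.14 and 0.10) were not called. Of 73 cytosolic ribosomal protein rows 26 were higher and 1 lower in KO1, 13 and 2 in KO2 and 22 and 2 in the mean of both lines. In both lines 12 were higher and 1 lower, 11 and 1 adjusted over the list alone, and 5 and 1 kept the call whichever library was left out. The camera adjusted p of this list was 9.6e-06 in KO1 and 1.5e-04 in the mean of both lines, with an adjusted p of 0.697 and 0.682 with an estimated correlation. In KO2 it was 0.0551, and by fry the list passed in none of the 3 comparisons with WT (0.0773, 0.192 and 0.0574 in KO1, KO2 and the mean). RPS2 rose by 1.02 ± 0.08 and 0.66 ± 0.08, RPL13 by 0.65 and 0.67 and RPL10 (over DNASE1L1) by 0.28 and 0.98, and RPL22 (over RNF207) fell by 1.63 and 1.39. Read through the opposite-strand gene, 15 ribosomal protein genes had 1 higher and 2 lower in both lines, 2 and 2 adjusted over the list alone, with an adjusted p of 0.630 by camera. DIPK1A, over RPL5, fell by 0.46 and 0.88 and kept that call without any 1 library.

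**Figure D4:**
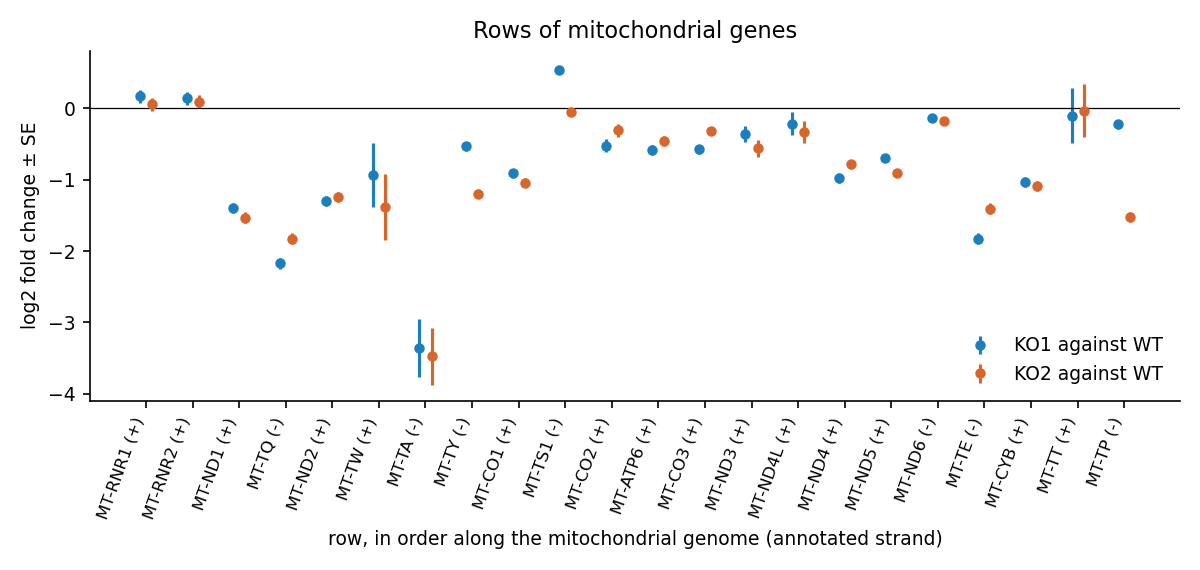
Log2 fold change against WT, with SE, of rows along the mitochondrial genome in KO1 and KO2, with the annotated strand of each row. Rows MT-ND1 to MT-CYB lie below 0 except MT-TS1 in KO1, at 0.54.

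The mean of both lines against WT set 1748 rows higher and 2261 lower, and with upper-quartile factors 2079 higher and 1935 lower. SLC8A1-AS1 and KRT38 were again among them, and 1172 rows changed at least 2-fold. When the difference between the lines entered the error, in a fit of 4 knockout against 2 WT libraries, 1223 rows were called. The authors' deposited table compares the same libraries. The authors' deposited table held 1164 rows at q under 0.05, 476 higher and 688 lower in knockout, with KRT38 at −8.83 and MT-ND1 at −1.43. Of the rows at that q in the authors' deposited table, 1134 were tested here, and all 1134 were called with the same sign in the mean of both lines and 1120 in both lines separately. The fit of the same form, with 4 knockout against 2 WT libraries, called 1061 of them with the same sign. Log2 fold changes in the authors' deposited table correlated at 0.990 with those of the mean of both lines across 10422 shared rows.

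KO1 and KO2 differed from each other at rows that 1 line gained or lost. NHLH2 had 172 and 154 reads in KO1 and 1 and 0 in KO2. FSTL5 had none in KO1 and 362 and 347 in KO2, at least 204-fold higher in KO2. PPP4R1L and ANKRD60, adjacent on chromosome 20, had 344 and 375 and 49 and 56 reads in KO2, with 1 and 0 and with none in KO1. TMEM229B had 232 and 252 reads in KO1, 165 and 239 in WT, and 1 and 4 in KO2. VIM-AS1, over the intermediate filament gene VIM, was at −0.10 ± 0.05 in KO1 and 0.61 ± 0.05 in KO2. In all, 1429 rows were higher in KO1 and 1460 lower, by the direct edgeR contrast, and 552 of them were also changed in both lines against WT. With upper-quartile factors 1664 were higher in KO1 and 1297 lower. Rows of whole regions shifted together. On chromosome 14 the median log2 fold change was −0.01 in KO1 and −0.46 in KO2, on chromosome 7 it was −0.07 and −0.47, on chromosome 22 it was 0.09 and −0.24, and on chromosome 10 it was −0.48 and −0.35. In the bin of chromosome 1 from 230000001 to 240000000 it was 0.83 and 0.86. That bin holds AL160408.2, over IRF2BP2 (a transcriptional corepressor), which rose by 1.04 and 1.49.

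**Figure D5:**
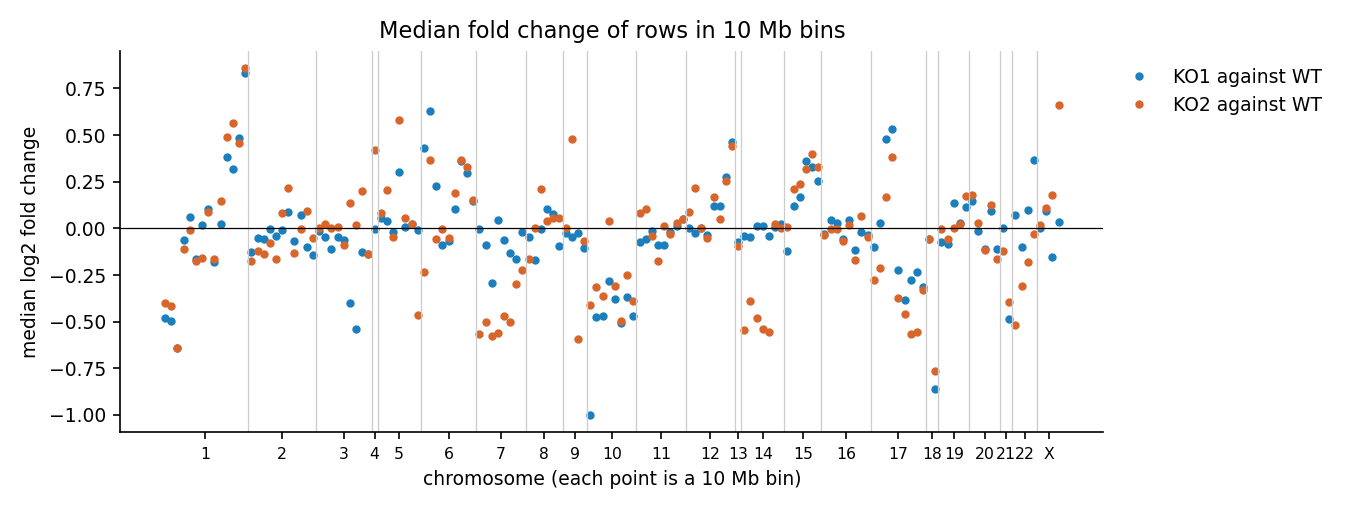
Median log2 fold change against WT of rows in 146 bins of 10 Mb, ordered along the chromosomes. Bins of chromosome 7 lie lower in KO2 than in KO1, and those of chromosome 10 lie below 0 in both lines except the bin from 80000001 to 90000000 in KO2, at 0.04.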

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

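The test of carry-over at a constant rate in the mitochondrial genome, the share of reads in ribosomal protein rows and the test of the shared WT libraries were chosen only after the result was seen. The first of the tests of strand, the median percentile of ribosomal protein rows among protein-coding rows, came out at an undecided value, 86.8, and was replaced by the share. The correlation of counts with opposite-strand bases was added after the correlation of row pairs had missed its bound, with its own result unseen.

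KO1 and KO2 differed from each other at 2889 rows by the direct edgeR contrast, and 34 of the 111 tested named rows were among them. Given as KO1 minus KO2 on the log2 scale, rows gained or lost by 1 line had large differences, whose fitted size depends on the prior count where a line had no reads. NHLH2 was at 8.22, SSC4D at 7.84, TMEM229B at 6.74, SNX18P24 at 5.92 and ZFHX4-AS1 at 4.16, while FSTL5 was at −11.36, PUDP at −9.15, PPP4R1L at −8.97, ANKRD60 at −8.60 and PPIAP90 at −8.14. SLC8A1-AS1 (1.04) and RAC1P9 (1.36) were more abundant in KO1. CDKN2B-AS1 (−0.29) was lower there. TRMT112, the partner of THUMPD2, was at 0.43, and LARP7, which binds 7SK RNA and U6, at 1.62. Of the list members, RPS2 (0.35), MT-ND5 (0.21), SYVN1 (0.32), PPIE (−0.73), SLC16A8 (−0.42), IMPDH2 (−0.46), TYMS (−0.43), RPL10 (−0.71) and KRT18 (−1.13) also differed between the lines.

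Another 8 differences between the lines were called with all libraries and ended when 1 was left out. MT-ND4 (−0.19) was at −0.05 without KO1 library 1 and −0.15 without KO2 library 1, and JSRP1 (−0.16) at −0.08 without KO1 library 1. SRSF9 (0.23) was not called without either KO2 library, at 0.21 and 0.23. MAK (0.40) was at 0.35 without KO1 library 1 and 0.24 without KO2 library 2, and PDE6C (−0.89) at −0.73 without KO1 library 2 and −0.74 without KO2 library 2. Without either KO1 library WHRN (−0.80) was at −0.70 and −0.90 and DPYD-AS1 (−1.13) at −1.01 and −1.26, and without either KO2 library at −0.89 and −0.71 and at −1.07 and −1.21. ATP5MF (0.49) was not called without KO1 library 1 (0.49), KO1 library 2 (0.49), KO2 library 1 (0.47), KO2 library 2 (0.50) or WT library 2 (0.49).

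Abundant genes had few reads, and rows on the strand opposite to them had many. Strong antisense transcription counted on the transcribed strand was argued against by the ribosomal protein rows, which held 0.252% of all counts where such abundant mRNAs would need several percent. That share is part of the same pattern of low counts that prompted the test, so it is not separate evidence. Assignment of reads to the strand opposite the transcribed gene remains a candidate explanation, but both tests of it fell short of bounds set in advance. Pairs of rows over the same opposite-strand gene correlated at 0.548 between the lines across 267 pairs (bootstrap 95% interval 0.344 to 0.723, bound 0.7), against 0.234 in 1973 neighbouring pairs over different genes, which lay farther apart. The Spearman correlation of mean count with opposite-strand bases was 0.287 (bound 0.3), against 0.00868 with the whole exonic length.

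Fold changes of rows in the same 10 Mb bin shifted together. For differences between the lines, the shared WT libraries alone were argued against. There, bin medians of KO1 minus KO2, where WT does not enter, had an SD of 0.226 against at most 0.105 in 1000 shuffles. GC content was argued against there too, since the SD was 0.223 after removal of its trend. Neither test covers shifts common to both lines against WT, to which the shared WT libraries may add. Copy number differences between the lines may underlie the shifts between them. Bin medians of KO1 minus KO2 from rows on the plus and on the minus strand correlated at 0.733 across 145 bins. Without rows whose opposite-strand gene has a tested row of its own, the correlation was 0.638 across 49 bins. Another regional process could also give such correlations. For shifts shared by both lines, with 1 WT line, a change of copy number and an effect of the knockout on a region are confounded. The medians of KO1 and KO2 were −0.07 and −0.47 on chromosome 7 and −0.01 and −0.46 on chromosome 14. For these 2 chromosomes the values argue against an effect of the same size in both knockout lines.

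Of 12 mitochondrial respiratory chain rows 11 were lower in both lines (camera adjusted p 8.2e-06 in their mean, and an adjusted p of 0.682 with an estimated correlation), while MT-TS1 rose by 0.54 in KO1 and the ribosomal RNA rows were not called. The ribosomal protein list passed upward in KO1 and in the mean of both lines (9.6e-06 and 1.5e-04, and an adjusted p of 0.697 and 0.682 with an estimated correlation) and did not pass in KO2 (0.0551). Carry-over of wrong-strand reads from mitochondrial mRNAs at a constant rate was argued against, since the MT-CO1 row changed by −0.99 log2 units more than MT-TS1, the row over the end of that mRNA, in the line where they differed least. More carry-over in the knockout libraries may contribute to the ribosomal protein change and stays open, since protein-coding rows with no opposite-strand gene had a median log2 fold change of 0.13 (bootstrap 95% interval 0.11 to 0.15), 40.2% of the ribosomal protein median, between the bounds set for the test. An effect of the knockout on either group remains open and was not separated from differences between the lines.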

How the results depend on the processing

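The bin offsets, the restriction to rows over opposite-strand exons and the reading of lists through the opposite-strand gene were chosen only after the result was seen. Under a fold threshold of 1.2 the counts were 1974 in KO1, 2695 in KO2, 2280 in the mean of both lines, 1545 between the lines and 1052 in both lines. Over opposite-strand exons alone, among 5423 tested rows, they were 1874, 2216, 2142, 1732 and 1125. A 2-group fit, in which the spread between the lines enters the error, called 1223 for the mean of both lines. Without 1 library the counts ran from 2575 to 3411 in KO1, 3228 to 4541 in KO2, 2943 to 4076 in the mean of both lines, 2118 to 3007 between the lines and 1468 to 1851 in both lines. The fold threshold is stricter, the restriction to opposite-strand exons tests fewer rows and the 2-group fit has a larger error, each by construction. The other settings, the fits without 1 library included, kept these counts within 1.5 times. DESeq2 gave the fewest calls of these other settings, 2246 in KO1, 2812 in KO2, 2727 in the mean of both lines, 1995 between the lines and 1279 in both lines. With edgeR the counts were 3350, 4118, 4009, 2889 and 1916. Of 87 named rows called in both lines, 43 lost that call in at least 1 setting, in 214 cases of a row and a setting, the fold threshold and the restriction to opposite-strand exons left aside. Among named values of the mean of both lines, and of KO1 against KO2 for rows named by that contrast, 1740 kept their direction and side of the threshold, 75 fell short of it and 1 reversed. In the mean of both lines MT-ND6 went to 0.56 under the bin offset with the mitochondrial genome as a bin, by its construction, since it subtracts the median of the other mitochondrial rows. The calls in both lines of MT-ND3, MT-ND4, MT-ND5, MT-ATP6, MT-CO2, MT-CO3, MT-TP and MT-TY ended there by the same construction. By DESeq2 the calls in both lines ended for KRT35, TSIX, MT-ND6, PPIE, MMP9, RPGRIP1, IMPDH2, MAK, PDE6C, GNAT1, VLDLR, TYMS, MCM3, MCM4, GINS3, PRC1, UBE2S, DHCR7, BNIP3L, COX5A, ATP5MC3, ATP5MF, INSM1, PCDHGC3, SNHG17, PTBP1, FSCN2, PRPS1, MT-CO2, MT-ND3 and DINOL. With upper-quartile factors they ended for MT-ND6, PPIE, MMP9, IMPDH2, TYMS, BNIP3L, ATP5MF, SYVN1, FSCN2, MT-ND3 and MT-TP. With limma-voom they ended for DHCR7, MAK, MCM4, MMP9, PCDHGC3, SNHG17, VLDLR and DINOL. With no filter on low counts they ended for ATP5MF, DHCR7, GINS3, MAK, MMP9, PPIE, SNHG17, VLDLR, FSCN2 and PRPS1, and with the filter of 1 CPM in 2 libraries for MMP9 and VLDLR. With the 10 Mb bin offset they ended for TSIX, GATC, ZACN, CLK3, PPIE, SNRNP35, NPLOC4, VTN, MMP9, MAK, FSCN2, PDE6C, PMEL, VLDLR, SYVN1, PKM, TYMS, PRC1, GINS3, UBE2S, BNIP3L, COX5A, ATP5MF, INSM1, SNHG17, HIF1AN and CFAP126. The call of RPL6P24, over PRPF18, ended with that offset too. Of the values of list tests in the mean of both lines, 259 were kept, and 2 were lost, those of the mitochondrial and ribosomal protein lists, with an adjusted p of 0.682 each under an estimated correlation. In single lines by row name the camera calls of the ATF4, mitochondrial and ribosomal protein lists in KO1 (0.697 each) and of the mitochondrial list in KO2 (0.880) were also lost under an estimated correlation. No list passed with an estimated correlation in any comparison, by row name or through the opposite-strand gene. The power of that setting was not measured here, so these losses cannot tell a weak test from an absent change.

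The labels do not say that replicate numbers pair the libraries. Deviations of libraries with the same number correlated at −0.0286 between WT and KO1 and at −0.0206 in the other pairs of groups. With the replicate block the counts were 3147, 3944, 3789, 2729 and 1822, in the order above. The calls in both lines of MT-ND6, PPIE, MMP9, MCM4, GINS3, INSM1, VLDLR, SNHG17 and ATP5MF ended with it, each in 1 line, where the adjusted p ran from 0.0502 for SNHG17 to 0.0693 for MT-ND6. No value was possible for THUMPD2, which was not tested. The counted reads per row limit what could be called. A 2-fold change was recovered in 43.5% of simulated rows for both lines, and in 86.0% of those with a mean count of at least 50. With the strand setting not given, the counted reads need not reflect the depth of sequencing.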

Other observations

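The rows in this part were chosen only after the result was seen, from the fits planned for all rows. SERTAD4-AS1, over SERTAD4, rose by 4.93 ± 0.27 and 4.12 ± 0.28 (log2 ± SE, n = 2 against 2). AL109930.1, over the zinc finger gene TSHZ2, went from 4 and 6 reads in WT to 83 and 54 in KO1 and 126 and 135 in KO2. AC078860.1, over LGR5, a receptor that marks epithelial stem cells, rose by 2.03 and 2.56, and DEC1, over the matrix glycoprotein gene TNC, by 2.99 and 2.67. In the other direction, AC091980.2, over the homeobox gene TLX3, fell from 197 and 192 reads to 2 and 9 in KO1 and 22 and 23 in KO2. AC023194.3, over ATP6V0D2, a subunit of the vacuolar proton pump, had no reads in WT, 115 and 92 in KO1 and 30 and 31 in KO2.

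AL133375.1, over the cullin gene CUL9, fell by 4.66 in KO1 and fell by 3.71 in KO2. TMEM120B, over 2542 exonic bases of the small GTPase gene RHOF, fell by 2.25 and 1.58, ERCC2, over the kinesin light chain gene KLC3, by 1.92 and 2.09, and DEPP1, over RASSF4, by 1.96 and 2.81. AC011503.1 and AC024563.1, over the zinc finger genes ZNF726 and ZNF492, had 64 and 64 and 44 and 41 reads in WT and none in KO1. They kept 7 and 13 and 6 and 5 reads in KO2. These calls held in both lines whichever library was left out.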
